A study of Mus musculus with 6 samples.

How the data were processed

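The deposited files are sparse matrices of UMI counts per gene and cell barcode, with 1 matrix per library. Reads were aligned and counted with Cell Ranger 8.0.1 against mm10, per the submitters' processing notes. The matrices of the enriched fraction carry version 8.0.1 and those of the depleted fraction version 7.0.0, per the file headers, and their feature lists hold 32285 and 54752 genes. The fractions were therefore never pooled, and were compared only over shared gene identifiers. The settings of cell calling and the handling of reads that match several genes are not given in the sources used here. Gene positions came from the GENCODE vM21 annotation of GRCm38 (mm10), in which 32235 and 54723 of the identifiers were found.

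Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. The mitochondrial limit removed 7.94%, 4.52% and 4.73% of barcodes from the naive, YUMM1.7 and YUMMER1.7 libraries of the enriched fraction, and 6.01%, 12.3% and 8.21% from those of the depleted fraction. Doublets were scored per library with Scrublet. Its automatic thresholds marked between 0% and 2.47% of cells, so the cells above the 95th percentile of the scores were removed from every library, which were between 4.37% and 4.96% of cells. Each fraction was scaled to 10000 UMIs per cell, log-transformed and clustered (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). Immunoglobulin, T cell receptor, mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out of the clustering. No correction was made for free RNA or between libraries.

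Clusters were named from fixed markers of 27 classes. A class could name a cluster when at least 3 of its markers were detected in at least 10% of the cells and lay above the rest by a log2 fold over 0.5. The mean log2 fold over all markers of the class also had to be at least 0.5. The class with most markers among the 10 leading genes was taken, then the highest mean fold. A cluster stayed unnamed when no class met these limits or when another class had more markers among its leading genes. It also stayed unnamed when it was shallow and its leading genes did not favour 1 class. Clusters 9, 12 and 25 of the enriched fraction stayed unnamed, with 4.10%, 9.78% and 6.00%, 4.88%, 4.12% and 3.56%, and 1.14%, 3.03% and 2.77% of kept cells in the naive, YUMM1.7 and YUMMER1.7 libraries. In the depleted fraction clusters 3, 14 and 21 stayed unnamed, with 8.31%, 5.22% and 3.65%, 1.97%, 2.43% and 2.06%, and 0.0405%, 1.75% and 25.0%. The naming rule and the rule for doublets were completed after the data were seen. Interferon genes lead monocyte cluster 8 and unnamed cluster 3 of the depleted fraction, early response genes such as Egr3 and Myc lead B cell cluster 5 of the depleted fraction, and Ccl3 and Il6 lead 1 of the 2 mast cell and basophil clusters of the enriched fraction, the other being led by Mcpt4 and Cma1.

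UMIs were summed per class and library and given as CPM, scaled to the sum of the class in that library. Log2 ratios have exact conditional binomial 95% intervals and shares have Clopper-Pearson intervals, all for counting error only. Within each class, genes were named by a fixed rule: those with the largest difference of both tumour libraries from naive, and those with the largest difference between the tumour libraries, ranked by the interval bound nearest 0. The rule took 2 genes per direction in the enriched and 3 in the depleted fraction. It required at least 50 UMIs and 50 CPM in the higher library and a CPM at least 0.5 times that of the other cells, and left out the gene families named above and unnamed gene models. Genes among the 10 leading genes of a cluster of their class are not reported. The text gives a part of the genes so named, and members of gene lists with large ratios as examples.

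For each of 18 fixed gene lists the median log2 ratio over members with at least 10 UMIs was placed among 10000 random lists of the same size matched on CPM. Lists below the 2.5th or above the 97.5th percentile are put forward, as a description of these libraries. The lists were type I interferon response (25 genes), interferon gamma response (23), MHC class I presentation (15), MHC class II presentation (10), DC maturation and co-stimulation (18), immune checkpoint and regulatory (16), inflammatory cytokines and chemokines (19), complement (14), lipid and lysosomal (18), hypoxia and glycolysis (18), proliferation (22), dissociation and heat shock (20), reticular homeostatic factors (17), extracellular matrix (30), myofibroblast and contractile (18), leukocyte adhesion and high endothelial (17), angiogenic and tip cell (17), and lymphatic identity and scavenging (19). The samples, the comparisons, the lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Lymphocyte classes and the leukocytes of the depleted fraction were added to the expression comparisons afterwards. Stromal cells of the naive library were left out of expression comparisons because there were 39 of them, and mast cells and innate lymphoid cells of the depleted fraction are not reported.

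The steps were tested on simulated data. For monocytes, YUMM1.7 over naive, with 3258 genes of which 200 were changed, the interval excluded 0 in the right direction for 50 of 50 genes at each of the folds 1.2, 1.5, 2 and 4, and held the true ratio for 94.9% of genes. For fibroblastic cells, YUMMER1.7 over YUMM1.7, with 3547 genes, this was 45 of 50 at a fold of 1.2 and 50 of 50 at folds of 1.5, 2 and 4, and 95.8% of genes. Lists of 20 genes with no shift passed the 97.5th percentile in 3.0% and 4.0% of draws, and lists shifted by a log2 ratio of 0.2 in 99.5% and 99.0%. Lists with no shift also fell below the lower limit for lists in 6 and 12 of 200 draws. These rates hold for the simulated data, and were not measured in real lists of co-expressed genes. Alternatives were TMM scaling from edgeR, another CPM total, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), cells thinned to 2000 UMIs, doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, another denominator for shares, and list members with at least 50 UMIs. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.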

Results

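Single-cell 3′ RNA libraries were made from inguinal and axillary lymph nodes of C57Bl/6 mice that carried a YUMM1.7 melanoma, a YUMMER1.7 melanoma or no tumour. YUMM1.7 is a mouse melanoma line, and YUMMER1.7 is a more immunogenic derivative of it obtained by ultraviolet mutagenesis. The nodes of several mice were pooled in each library. The 6 libraries covered 2 cell fractions, one enriched with CD11b and CD11c beads for myeloid cells and one depleted of CD45+ cells to enrich stroma, with 1 library per arm in each. The labels call the latter fraction depleted of CD45+ cells, whereas its protocol speaks of enriching stroma positively with CD45 beads, and CD45+ lymphocytes made up most of its cells in the naive and YUMM1.7 libraries, so what its shares stand for is uncertain. The enriched libraries held 86471908, 78305030 and 78551522 unique transcript counts (UMIs) in the naive, YUMM1.7 and YUMMER1.7 arms, and kept 9951, 7095 and 6466 cells with medians of 6708, 9408 and 10149 UMIs. The depleted libraries held 78240566, 76861915 and 67709285 UMIs, and kept 12356, 8301 and 6540 cells with medians of 4150, 4592 and 4901 UMIs. With 1 library per group no difference below has a replicate check, and each interval in brackets is a 95% interval that covers counting error only. Class names were given to clusters from fixed marker genes, so that monocyte stands for monocyte-like cells and likewise for the other classes.

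The first question was which myeloid cells took a larger or smaller share of the nodes that drain a tumour. Monocytes, blood-borne precursors of inflammatory macrophages and dendritic cells, made up 38.7% (37.3 to 40.1) of the myeloid cells in the YUMM1.7 library and 40.6% (39.1 to 42.1) in the YUMMER1.7 library, against 14.1% (13.2 to 15.01) in the naive library. Their share was 2.75 times (2.53 to 2.99) and 2.88 times (2.65 to 3.14) the naive share. CCR7+ migratory dendritic cells (DCs), which carry antigen from tissue into the node, made up 23.6% (22.4 to 24.9) and 23.1% (21.8 to 24.4), against 38.2% (37.0 to 39.5) in the naive library. The fall lay in cluster 5 (1438, 414 and 248 cells in the naive, YUMM1.7 and YUMMER1.7 libraries) and cluster 2 (252, 74 and 47). Cluster 6 held 391, 449 and 523 cells. In the depleted fraction migratory DCs went the other way, at 2.40%, 3.63% and 4.22% of all kept cells. Conventional type 1 DCs (cDC1), the cross-presenting subset, differed little, at 3.98% (3.49 to 4.52) in the naive, 4.19% (3.63 to 4.81) in the YUMM1.7 and 3.33% (2.81 to 3.92) in the YUMMER1.7 library. Mast cells and basophils were few, 17, 27 and 48 cells, and the rise lay in cluster 29, led by Ccl3 and Il6, with 0, 20 and 34 cells, while cluster 28, led by the mast cell protease Mcpt4, held 17, 7 and 14. Macrophages made up 16.7% of naive myeloid cells and 9.85% and 8.94% in the tumour arms, but this order was lost when the shallow macrophage cluster 13 was left out. T cells, carried through the beads, made up 16.5%, 5.06% and 6.46% of all kept cells, and the bead enrichment and the lower depth of the naive library can set any of these shares.

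**Figure D1:**
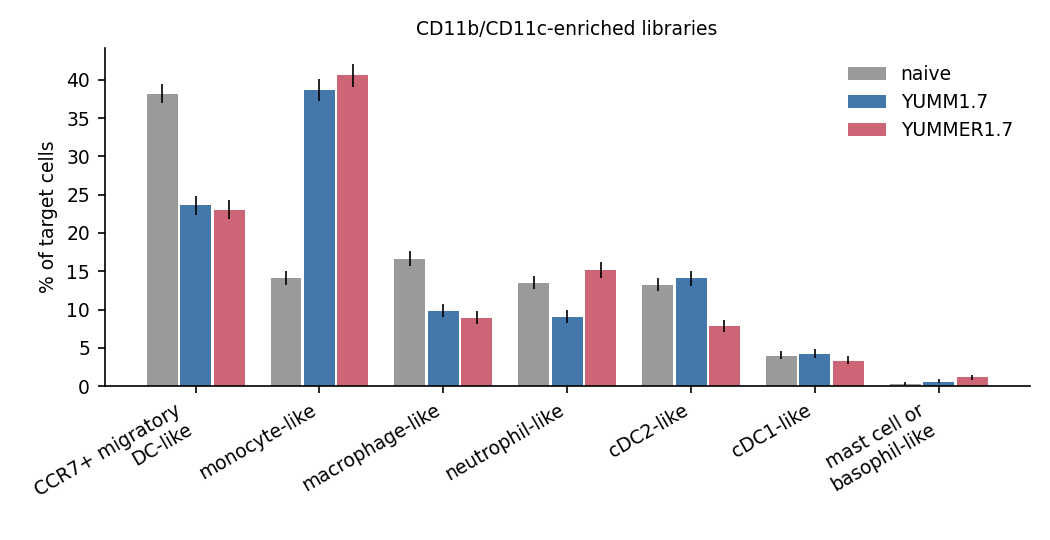
Share of myeloid target cells (%) per class in the naive, YUMM1.7 and YUMMER1.7 libraries of the CD11b/CD11c-enriched fraction; bars are shares and error bars exact 95% intervals for counting error. Monocytes stand at 14.1%, 38.7% and 40.6%, and CCR7+ migratory DCs at 38.2%, 23.6% and 23.1%.

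The second question was how the genes used by each myeloid class differed between tumour-draining and naive nodes. Interferon-stimulated genes, which restrict viruses and mark exposure to type I interferon, were higher in both tumour libraries in 7 of the 9 classes compared. In type 2 conventional DCs (cDC2) the median log2 ratio of the type I interferon list to naive was 0.82 for YUMM1.7 and 1.17 for YUMMER1.7, and in cDC1 0.46 and 1.25. Irf7, a transcription factor that amplifies interferon production, stood at 30.3, 69.1 and 92.4 CPM (UMI counts scaled to the total of the class in each library) in cDC2 and at 32.6, 49.2 and 85.1 CPM in cDC1 of the naive, YUMM1.7 and YUMMER1.7 libraries. Rtp4, an interferon-induced antiviral gene, stood at 23.5, 53.9 and 77.0 CPM in cDC2. The list was also higher in neutrophils (0.72 and 0.54), monocytes (0.54 and 0.37), natural killer (NK) cells (0.39 and 0.40), T cells (0.31 and 0.40) and, less so, macrophages (0.11 and 0.20, with −0.08 for YUMM1.7 under the stricter cell filter). In neutrophil cluster 3 alone the YUMMER1.7 median was 0.85, and cluster 4 held 6.07%, 6.97% and 18.1% of neutrophils. In neutrophils Isg15, which encodes a ubiquitin-like modifier, stood at 447, 741 and 841 CPM. In monocytes Xaf1, a pro-apoptotic interferon target, stood at 59.7, 102 and 95.7 CPM, and the list median was 0.42 in both arms without cluster 8, whose leading genes are interferon targets. B cells (−0.18 and 0.19) and migratory DCs (−0.20 and −0.08) lay outside this pattern by their medians. The summed CPM of the list was nonetheless higher in migratory DCs of both tumour arms (959, 1034 and 1185 in the naive, YUMM1.7 and YUMMER1.7 libraries). In B cells the sum was 1199, 1253 and 1538 CPM, and the YUMM1.7 gain was within counting error. The interferon gamma list was higher in monocytes (0.30 and 0.28) and neutrophils (0.35 and 0.24). Both arms were compared with the same naive library, so a low value there raises both ratios.

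Maturation and inflammatory genes were lower in conventional DCs of both tumour arms. Cd80, a co-stimulatory ligand for T cells, stood at 121, 66.8 and 61.9 CPM in cDC1 of the naive, YUMM1.7 and YUMMER1.7 libraries, and Cd83, a maturation marker, at 741, 504 and 374 CPM. In cDC2 Cxcl2, a neutrophil chemoattractant, stood at 86.0, 27.3 and 16.7 CPM, and Tnfaip3, a brake on NF-κB signalling, at 324, 136 and 111 CPM. The maturation list had medians of −0.32 and −0.32 in cDC1 and −0.44 and −0.75 in cDC2, and the inflammatory list −0.50 and −0.41 in cDC1 and −0.73 and −0.67 in cDC2. Migratory DCs, which are rich in some members of the maturation list, also took a smaller share in both tumour libraries, and no correction was made for free RNA. Lpl, which releases fatty acids from lipoproteins, was lower in cDC2 (154, 44.2 and 21.6 CPM; log2 −1.80, −1.98 to −1.63, and −2.84, −3.16 to −2.54) and in monocytes (57.0, 12.1 and 10.1 CPM). Cd36, a scavenger receptor for lipids, was lower in monocytes (69.0, 22.4 and 15.1 CPM), and the lipid list had medians of −0.70 and −0.60 in cDC2. At Leiden resolution 2 Lpl led 1 of the cDC2 clusters, with 377, 123 and 52 cells against 312, 433 and 222 in the other, so the cDC2 values mix clusters whose shares differed. Jdp2, a repressor of AP-1 target genes, was lower in cDC1 (237, 73.6 and 53.8 CPM; log2 −1.69, −1.88 to −1.50, and −2.14, −2.39 to −1.90), where Tspo, a mitochondrial cholesterol-binding protein, was higher (244, 439 and 506 CPM). The complement list (−0.80 and −0.70) and the reticular homeostatic list (−0.44 and −0.60) were also lower in cDC1, and the hypoxia and glycolysis list was higher (0.29 and 0.41). The complement list was similarly lower in B cells (−0.79 and −0.66) and T cells (−0.55 and −0.92) of these libraries. Its fall was thus not confined to cDC1, and a difference in free RNA was not excluded. With each cell thinned to 2000 UMIs the inflammatory list in cDC1 turned to 0.13 for YUMM1.7, and over members with at least 50 UMIs the reticular list turned to 0.10 for YUMMER1.7.

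Summed over macrophages, Retnla and Fn1 were higher in both tumour arms. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a marker of alternatively activated macrophages, stood at 39.1, 617 and 567 CPM in the naive, YUMM1.7 and YUMMER1.7 libraries (log2 3.98, 3.77 to 4.20, and 3.86, 3.65 to 4.07). Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), which encodes fibronectin, stood at 21.5, 272 and 246 CPM (log2 3.66, 3.38 to 3.96, and 3.52, 3.23 to 3.81). Within macrophage cluster 19 alone Retnla stood at 67.0, 1121 and 838 CPM and Fn1 at 31.4, 493 and 362 CPM. At Leiden resolution 2 both genes led a macrophage cluster of 6, 31 and 41 cells, so the class values are sums over unlike macrophages. Il22ra2, a decoy receptor for interleukin 22, was lower in macrophages (236, 35.5 and 40.7 CPM), as was Bpifb2, a secreted lipid-binding protein (73.6, 10.9 and 4.66 CPM). Among complement genes C4b stood at 21.7, 139 and 138 CPM, and the complement list had medians of 0.30 and 0.24. The inflammatory list was 0.18 and 0.65 against naive, with Cxcl2 at 80.3, 155 and 217 CPM in macrophages, and its YUMM1.7 median was −0.03 under the stricter cell filter. Most macrophages of the naive library belonged to the shallow cluster 13 and most of the YUMMER1.7 library to cluster 19.

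In migratory DCs Scin, an actin-severing protein, was higher in both tumour arms, at 16.9, 55.9 and 60.9 CPM (log2 1.73, 1.55 to 1.92, and 1.85, 1.67 to 2.04), and so was Btla, an inhibitory receptor, at 22.9, 88.2 and 83.8 CPM (log2 1.94, 1.79 to 2.10, and 1.87, 1.71 to 2.03). Mucl1, a secreted mucin-like gene, was lower (log2 −3.32, −3.72 to −2.95, and −6.29, −7.61 to −5.25). Over the class the maturation list was higher (0.22 and 0.28), with Cd80 at 102, 188 and 189 CPM in these cells, and the major histocompatibility complex (MHC) class II list was higher (0.44 and 0.49). The myofibroblast and contractile list (0.31 and 0.35) and the dissociation and heat shock list (0.15 and 0.37) were higher as well, and the inflammatory (−0.34 and −0.39, with 0.04 for YUMM1.7 in thinned cells) and lipid (−0.21 and −0.50) lists were lower. Most migratory DCs lay in cluster 5 in the naive library and the largest part in cluster 6 in both tumour libraries. Within cluster 5 the maturation medians were −0.11 and −0.15, and within cluster 6 the MHC class II medians were −0.58 and −0.26, so the class values mix these clusters. In neutrophils Lyz1, a lysozyme, was lower (227, 30.3 and 15.3 CPM), and in T cells Tnfrsf4, a co-stimulatory receptor, was higher (24.7, 61.5 and 107 CPM). The lymphatic identity and scavenging list, with 9 and 8 members measured, had medians of −0.997 and −1.69 in cDC2, and −0.42 and −0.39 over the 5 members with at least 50 UMIs.

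**Figure D2:**
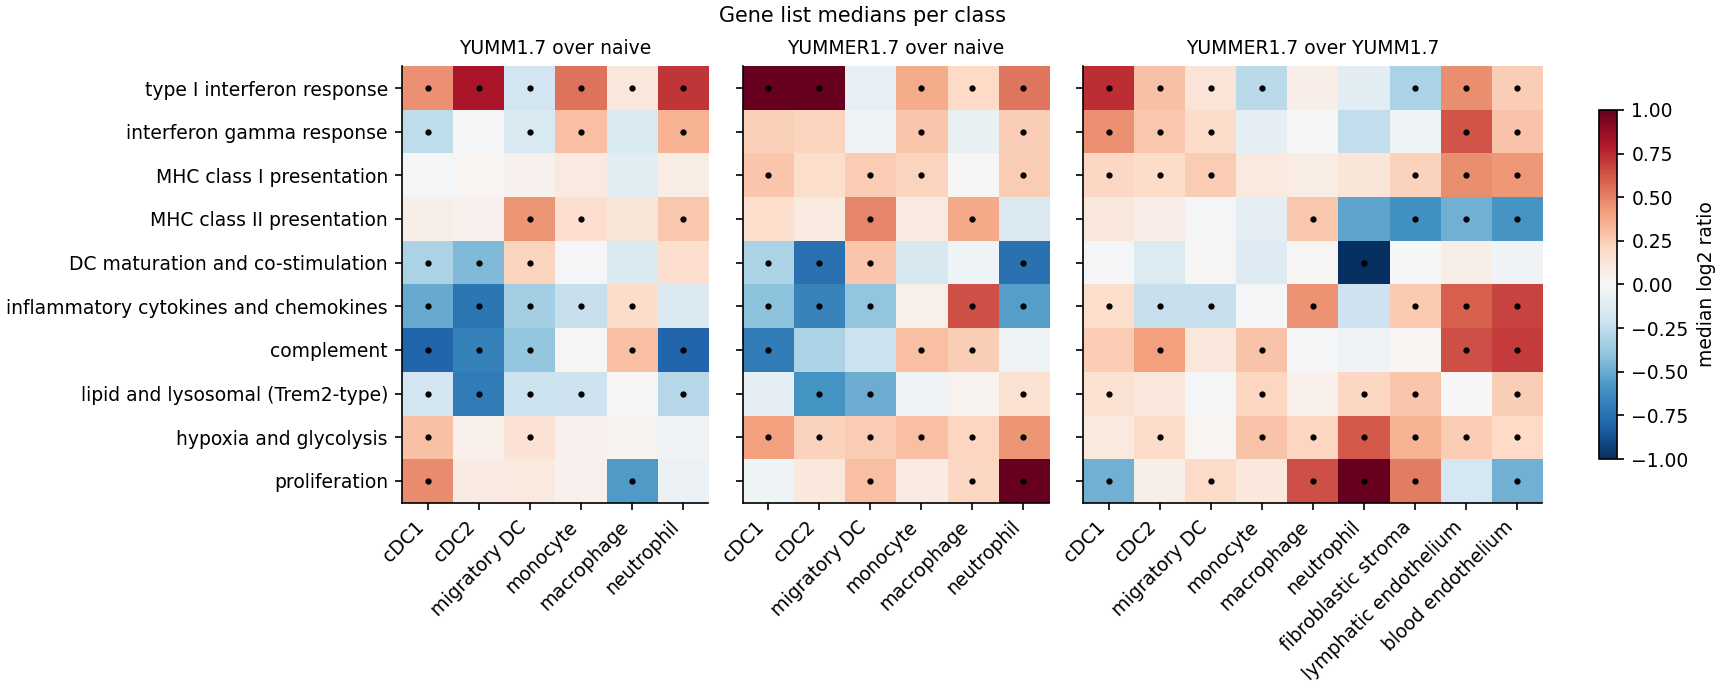
Median log2 ratio of the fixed gene lists per class, for each tumour library over naive and for YUMMER1.7 over YUMM1.7; colour gives the median, and dots mark medians among the lowest or highest 2.5% of matched random lists. The type I interferon list stands at 0.82 and 1.17 over naive in cDC2 and at 0.74 between the tumours in cDC1.

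The third question was whether nodes that drain the more immunogenic YUMMER1.7 tumour differed from those that drain YUMM1.7. Interferon and antigen presentation genes were higher in the DCs of the YUMMER1.7 library. In cDC1 the type I interferon list had a median log2 ratio of 0.74 and the interferon gamma list one of 0.46, with Serpina3g, an interferon-induced protease inhibitor, at 51.3 CPM in the YUMM1.7 and 113 CPM in the YUMMER1.7 library. The MHC class I list was higher in cDC1 (0.21), cDC2 (0.18) and migratory DCs (0.25), though it was 0.099 in thinned cDC1 and 0.035 in migratory DC cluster 5 alone. In migratory DCs Psmb9, an immunoproteasome subunit, stood at 425 and 556 CPM and Tap1, a peptide transporter, at 147 and 189 CPM. The type I interferon list was higher in cDC2 (0.30) and lower in monocytes (−0.27), of which cluster 8 held 11.9% and 7.97%. Ifitm1, an antiviral membrane protein, stood at 107 and 484 CPM in cDC2 (log2 2.18, 2.06 to 2.29), while neutrophils of the same libraries held 1275 and 3265 CPM and monocytes 23.3 and 87.9 CPM. In migratory DCs Rnaset2a stood at 148 and 394 CPM and Rnaset2b at 33.9 and 103 CPM; these lysosomal ribonuclease genes are near-identical copies whose reads could be split between them. Prkg1, a cyclic GMP-dependent kinase, was lower in migratory DCs of the YUMMER1.7 library (52.2 and 23.1 CPM).

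Among the other myeloid classes, YUMMER1.7 macrophages had higher inflammatory genes (median 0.45), with Ptgs2, the inducible prostaglandin synthase, at 61.9 and 127 CPM in the YUMM1.7 and YUMMER1.7 libraries and Ccl2, a monocyte chemoattractant, at 173 and 293 CPM. Their MHC class II (0.27), hypoxia and glycolysis (0.21) and proliferation (0.65) lists were higher too, and Nrg1, a growth factor of the epidermal growth factor family, stood at 25.1 and 63.9 CPM. In monocytes Cd38, an enzyme that consumes NAD, stood at 27.7 and 85.7 CPM (log2 1.63, 1.48 to 1.77), and the complement (0.29), hypoxia and glycolysis (0.29) and lipid (0.21) lists were higher, with the complement factor Cfb at 108 and 168 CPM. Neutrophils of the YUMMER1.7 library held more Prtn3 (18.3 and 264 CPM) and Elane (21.8 and 227 CPM), granule proteases of immature neutrophils, and their proliferation median was 1.93. That median was −0.31 in neutrophil cluster 3 alone, so it came from the cells of cluster 4. Proliferation was lower in cDC1 (−0.48), of which the mitotic cluster 17 held 8.81% and 4.93%, as 17 and 7 cells, and higher in T cells (2.28), where Birc5, a mitotic gene, had a log2 ratio of 3.53 (2.91 to 4.22). At Leiden resolution 2 the cycling T cells formed a cluster of 2 YUMM1.7 and 27 YUMMER1.7 cells, and most T cells lay in cluster 1 in the YUMM1.7 library and the largest part in cluster 0 in the YUMMER1.7 library. Neutrophils made up 9.03% and 15.1% and cDC2 14.1% and 7.79% of myeloid cells, and both orders turned when each library was clustered on its own. The unnamed cluster 9 held 408, 694 and 388 cells in the naive, YUMM1.7 and YUMMER1.7 libraries. At Leiden resolution 0.5 its leading genes Ctnnd2, Scn3a and Klri1 also led the cDC2 cluster, of 1127, 1327 and 715 cells. All cDC2 values here therefore leave out a part of the cDC2-like cells.

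The fourth question was which cells the CD45-depleted fraction held and how the stroma of YUMMER1.7-draining nodes compared with that of YUMM1.7-draining nodes. Fibroblastic and endothelial cells made up 0.316% (0.225 to 0.431) of the naive, 7.36% (6.81 to 7.94) of the YUMM1.7 and 13.9% (13.1 to 14.8) of the YUMMER1.7 library, as 39, 611 and 912 cells. Fibroblastic cells, which build the reticular scaffold of the node, numbered 8, 276 and 431, lymphatic endothelial cells 21, 215 and 218, and blood endothelial cells 10, 120 and 263. B cells were the largest class at 57.2%, 50.2% and 35.2%, and T cells made up 22.3%, 12.1% and 2.84%. Plasma cells, which secrete antibody, made up 1.72% (1.49 to 1.9605), 9.50% (8.88 to 10.2) and 5.69% (5.14 to 6.28). Plasmacytoid DCs (pDCs), professional producers of type I interferon, made up 1.21%, 1.95% and 1.79%. Within the stroma of the YUMMER1.7 library, blood endothelium took a larger share than in the YUMM1.7 library (28.8% and 19.6%; log2 0.55, 0.24 to 0.88) and lymphatic endothelium a smaller one (23.9% and 35.2%; log2 −0.56, −0.84 to −0.28), though of all kept cells its share was higher (log2 0.36). The success of the depletion can set all of these shares, and the unnamed cluster 21, at 0.0405%, 1.75% and 25.0% of kept cells, was kept out of every class. It was still counted among all kept cells, so it lowered the other classes' shares of all kept cells most in the YUMMER1.7 library. With it left out, 11 of 18 log2 ratios of such shares moved outside their counting intervals. The order of pDCs between the tumour arms is therefore not read.

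**Figure D3:**
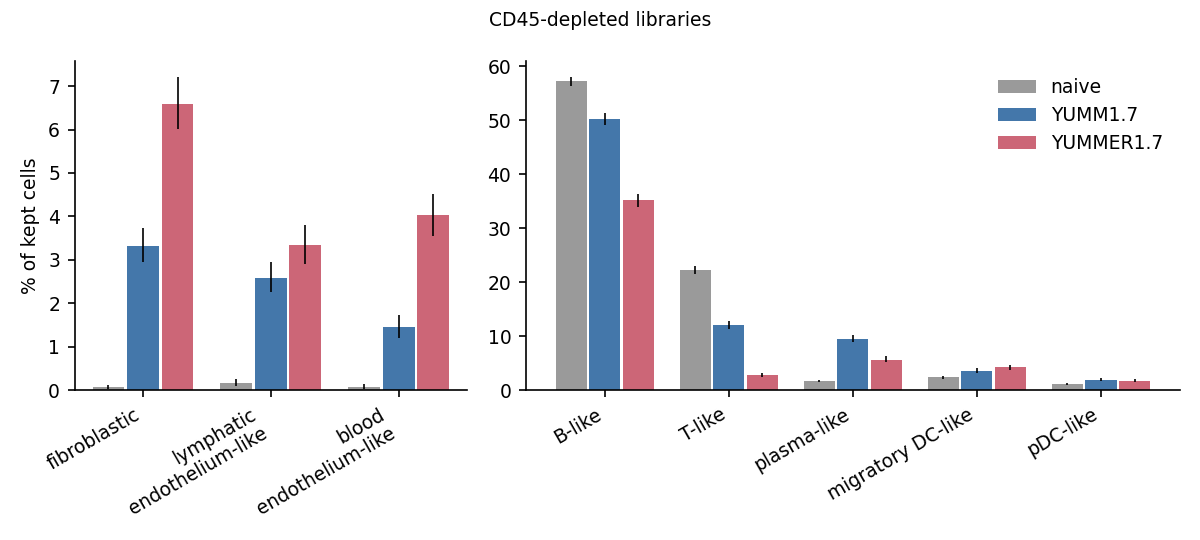
Share of all kept cells (%) per class in the naive, YUMM1.7 and YUMMER1.7 libraries of the CD45-depleted fraction; bars are shares and error bars exact 95% intervals for counting error. Fibroblastic cells stand at 0.0647%, 3.32% and 6.59%, and plasma cells at 1.72%, 9.50% and 5.69%.

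Stromal genes were compared between the tumour arms only, since the naive library held too few stromal cells. Lymphatic endothelium of the YUMMER1.7 library had higher interferon gamma (0.62), MHC class I (0.47), type I interferon (0.46), inflammatory (0.60), complement (0.65), immune checkpoint (0.30) and leukocyte adhesion (0.20, or −0.05 in thinned cells) lists. There H2-T23, a non-classical MHC class I molecule, stood at 284 CPM in the YUMM1.7 and 552 CPM in the YUMMER1.7 library, Gbp4, an interferon-induced GTPase, at 34.0 and 77.6 CPM, Cd274, the ligand of the inhibitory receptor PD-1, at 51.3 and 90.5 CPM, and Ptgs2 at 54.4 and 210.1 CPM. Ly6a, a stem cell and interferon-induced surface protein, stood at 128 and 402 CPM (log2 1.65, 1.51 to 1.79). Cluster 20, led by Ccl20, Cxcl9 and Cxcl10, held 32.1% and 40.8% of lymphatic endothelial cells, so these values mix clusters as well. Blood endothelium had higher MHC class I (0.44), interferon gamma (0.28) and extracellular matrix (0.41) lists and a lower proliferation list (−0.48, or 0.04 in thinned cells). In it Igfbp3, which binds insulin-like growth factors, stood at 85.6 and 333 CPM, Esm1, a marker of sprouting vessels, at 12.9 and 65.2 CPM, and Tagln, a contractile protein, at 89.0 and 18.6 CPM. At Leiden resolution 2 blood endothelium split into a capillary cluster of 35 and 104 cells and a high endothelial cluster of 85 and 158 cells, so its values mix clusters too. In fibroblastic cells Prg4, a joint lubricant, stood at 14.8 and 62.7 CPM (log2 2.08, 1.71 to 2.48), and Angptl4, an inhibitor of lipoprotein lipase, at 49.1 and 163 CPM (log2 1.73, 1.52 to 1.94). Their proliferation (0.51), heat shock (0.40), hypoxia and glycolysis (0.34), lipid (0.28) and MHC class I (0.23) lists were higher, and their extracellular matrix list was lower (−0.23), with Col14a1 at 361 and 239 CPM and Col6a3 at 525 and 351 CPM. The collagen-rich cluster 17 held 35.5% of fibroblastic cells in the YUMM1.7 and 25.8% in the YUMMER1.7 library, so these values mix clusters whose shares differed. Their angiogenic list was 0.14, and turned to −0.20 in thinned cells. The MHC class II list was lower in all 3 stromal classes (−0.60, −0.59 and −0.48), in libraries in which B cells, rich in these transcripts, made up 50.2% and 35.2% of cells. When the stromal cells were clustered again, 35 YUMM1.7 and 22 YUMMER1.7 cells formed a cluster led by B cell genes such as Bank1 and Cd79a, with H2-Aa and H2-Eb1. The stromal classes themselves thus held cells with B cell transcripts.

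Leukocytes of the same fraction could be compared with naive. In pDCs the type I interferon list was higher in both tumour arms (0.57 and 0.68), with Mx1, an antiviral GTPase, at 37.0, 66.9 and 66.6 CPM, and the inflammatory list was lower (−0.91 and −0.74). Nr4a3, an immediate early gene, stood at 197, 9.55 and 8.82 CPM in pDCs, and Ccl4, a chemokine, at 2887, 615 and 725 CPM. Nr4a3 was highest in the naive library in B cells (62.0, 39.1 and 35.9 CPM) and migratory DCs (246, 165 and 116 CPM) of this fraction too, so the difference was not confined to pDCs, and a difference in handling of that library was not excluded. T cells of the YUMMER1.7 library held more of the cytotoxic granule genes Gzma (6.50, 11.2 and 223 CPM) and Gzmb (28.1, 41.8 and 178 CPM). Cluster 15, named innate lymphoid, had Gzmb among its leading genes beside T cell genes. It was left out of these T cells in every arm, with 197, 90 and 132 cells. S100a6, a calcium-binding protein, stood at 204, 340 and 869.8 CPM in T cells. It rose in the order of the stromal share, so free stromal RNA was not excluded for it. In plasma cells the type I interferon list was lower (−0.85 and −0.58), and Crip1, a zinc-binding LIM protein, was higher (183, 466 and 454 CPM). Cluster 16 held 26.4% of plasma cells in the naive library and 49.7% and 52.4% in the tumour libraries, so these values mix clusters whose shares differed. B cells, most of which lay in clusters 0 and 4 in the naive library and in cluster 2 in the YUMMER1.7 library, held 161 CPM of H2-T23 in the YUMM1.7 and 264 CPM in the YUMMER1.7 arm. Collagen and other matrix transcripts in B cells (list median 4.04 and 4.85 over naive) and T cells (3.62 and 5.21) mirror the amount of stroma in each library, so stromal genes were not read in leukocytes.

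The last question was whether the difference from naive was alike in the 2 fractions, which share no library. Whether both fractions came from the same mice is not given in the sources used here, so likeness between them is no check in other animals. Across 2763 genes the log2 ratios of migratory DCs correlated between fractions for YUMM1.7 (Pearson 0.557, Spearman 0.522), and across 2783 genes for YUMMER1.7 (0.617 and 0.597); genes are not independent replicates. All 10 and all 23 genes that differed at least 2-fold in both fractions went the same way. Among them, named after their values were seen, Scin was higher in the depleted fraction as well (log2 1.76 and 1.91), and Pdcd1lg2, a ligand of PD-1, had a log2 ratio for YUMM1.7 of 1.06 in the enriched and 2.004 in the depleted fraction. The 10 genes for YUMM1.7 include Prkg1 (log2 1.44 and 5.41), for which free stromal RNA in the depleted fraction was not excluded. Some of the 10 and of the 23 genes are leading genes of migratory DC clusters of the enriched fraction. Cluster 5 held 65.8%, 38.1% and 25.2% of that class in the naive, YUMM1.7 and YUMMER1.7 libraries. A shift in the mix of migratory DCs, alike in both fractions, was thus not told apart from a change within cells. Btla did not repeat in migratory DCs of the depleted fraction (68.2, 87.1 and 66.2 CPM), nor did Cd80 (187, 183 and 213 CPM). B cells correlated less for YUMM1.7 (0.349 and 0.308) than for YUMMER1.7 (0.579 and 0.541). T cells did not correlate for YUMM1.7 (−0.019 and −0.035) and did for YUMMER1.7 (0.403 and 0.416). There 1 of the 2 genes that differed at least 2-fold in both fractions went the same way. Cluster 1, led by Cxcr6, Il23r and Zbtb16, held 45.4%, 55.4% and 28.9% of enriched T cells in the naive, YUMM1.7 and YUMMER1.7 libraries. No T cell cluster of the depleted fraction was led by these genes. The T cells compared were thus unlike between the fractions, and their mix differed between arms. The log2 ratio of the longest genes less that of the shortest, enriched then depleted, was −0.191 and 0.046 in T cells for YUMM1.7. It was −0.605 and −0.219 for YUMMER1.7. In B cells it was −0.352 and −0.015 for YUMM1.7, and −0.493 and −0.163 for YUMMER1.7. In migratory DCs, which correlated most, it was −0.073 and −0.15, and −0.193 and −0.263. A gene length bias shared by the fractions could raise these correlations, and this was not tested.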

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

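Of the tests below, the gene length tests over all the classes were written before their outcome was computed, and all others, with the one on the 4 classes named below, were chosen after the result was seen. The MHC class I list was higher in the YUMMER1.7 than in the YUMM1.7 library, among the highest 2.5% of matched random lists in 14 of 17 classes, although in migratory DC cluster 5 alone it was 0.035. Long genes were lower in the YUMMER1.7 libraries in every class, so gene length bias could raise a list of short genes. The list stayed there among random lists matched on CPM and gene span in 10 of the 14 classes, which argues against gene length bias as the whole cause there. In the other 4 (T cells and NK cells of the enriched fraction, fibroblastic cells and plasma cells) it did not, and gene length bias and a difference in these genes cannot be told apart. The interferon gamma list, which shares no gene with it, also stood among the highest 2.5% in 9 of the 14 classes, in line with a stronger interferon gamma signal in those, but in NK cells it was among the lowest 2.5% (median −0.31). A difference between libraries in handling stays open, untested.

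The type I interferon list was among the highest 2.5% of matched lists in both tumour libraries over naive in 7 of 9 enriched classes. All 7 classes stayed there among lists matched on gene span, which argues against gene length bias. Free RNA from the interferon-high monocytes of cluster 8 would add a like number of UMIs to every cell. The gain was taken as the difference in CPM times the mean UMIs per cell of the class in the tumour library. Of the 6 of these classes other than monocytes, 5 (cDC2, cDC1, macrophages, neutrophils and T cells) had over 3 times the gain of the class with the smallest gain (B cells for YUMM1.7 and NK cells for YUMMER1.7). This held beyond counting error in both tumour libraries, which argues against free RNA as the whole cause in those 5. It assumes that B cells did not lower these genes themselves, and with NK cells as the base for both, it held for 2 (cDC2 and neutrophils). For macrophages the cluster mix differed too, as shallow cluster 13 held 74.5% of the naive and 38.1% of the YUMM1.7 cells. By the plain difference in UMIs per cell, the smallest YUMM1.7 gain was in NK cells (0.728, against 2.13 in B cells). The form of this test, with the classes used as base, was changed after its values were seen. For the 1 class with a smaller gain, NK cells, free RNA from the interferon-high monocytes of cluster 8 and a rise of these genes in the cells cannot be told apart. The tumour itself, and a low level in the 1 naive library used for both ratios, stay open and were not tested.

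Fibroblastic and endothelial cells were nearly absent from the naive depleted library, at 39 cells. Had they been lost at the cell filter or in cell calling, their free RNA would remain, but B cells of the naive library held 0.0615 times (0.0540 to 0.0699) the extracellular matrix CPM of those of the YUMM1.7 library, which argues against that loss. Whether the nodes of naive mice held fewer stromal cells cannot be told apart from a difference in digestion or depletion: among enriched libraries the log2 ratio of the fibroblastic share, YUMM1.7 over naive, was 0.49 (−0.69 to 1.67) on 14 and 14 cells, which assumes alike carry-over.

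The remaining results differed between the fractions or belong to cells outside the comparisons, and the difference was not tested in any of them. The MHC class II list in migratory DCs was higher than naive in the enriched fraction (0.44 for YUMM1.7 and 0.49 for YUMMER1.7) and lower in the depleted fraction (−0.43 and −0.62). The complement list in B cells was lower than naive in the enriched fraction (−0.79 and −0.66) and higher in the depleted fraction (3.28 and 4.42). The complement list in T cells was likewise lower in the enriched (−0.55 and −0.92) and higher in the depleted fraction (3.99 and 4.15). Most of these members, such as C3 and Serping1, were abundant in fibroblastic cells, and free stromal RNA in the depleted libraries stays open for both, so they are not read as expression by lymphocytes. Cluster 21 of the depleted fraction, led by Ccl2, Fabp4, Cxcl1, Cxcl13 and Cxcl10, held 5, 145 and 1635 cells in the naive, YUMM1.7 and YUMMER1.7 libraries, 43.2 and 618 times the naive share, at 0.123 of the depth of its own samples.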

How the results depend on the processing

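Values are log2 ratios, with the reported value in brackets, and the cause was not tested unless a cause is named. Of 1077 recomputed values of named genes 1074 kept their direction, of 582 list medians 558, and of 297 shares 289. No fit of both fractions with the fraction as block was run. TMM scaling kept 293 of 294 list calls, the stricter filter 277 of 294, thinning 181 of 264, members with at least 50 UMIs 245 of 267, and span-matched lists, chosen after seeing the data, 264 of 294, while migratory DC cluster 5 alone kept 6 of 20, cluster 6 alone 12 of 20 and neutrophil cluster 3 alone 7 of 11. With each library clustered on its own, monocytes over naive were 1.74 [1.46] for YUMM1.7 and 2.03 [1.53] for YUMMER1.7, migratory DCs −0.29 [−0.69] for YUMM1.7 and macrophages −1.19 [−0.90] for YUMMER1.7; cDC2 reversed to 0.88 [−0.77] for YUMMER1.7 over naive and 0.68 [−0.85] over YUMM1.7, and neutrophils to −0.77 [0.16] and −0.59 [0.75]. With all kept cells as denominator, monocytes were 1.63 and 1.72, migratory DCs −0.52 and −0.53, macrophages −0.58 [−0.76] and −0.70, and between tumours fibroblastic cells 0.99 [0.07], blood endothelium 1.48 [0.55] and lymphatic endothelium 0.36 [−0.56, reversed], since stroma was a larger part of all YUMMER1.7 cells. Leiden resolution 2 gave −0.58 and −0.72 for macrophages and 0.99 for blood endothelium. The stricter filter gave monocytes 1.33 and 1.40, migratory DCs −0.87 for YUMMER1.7 [−0.73], macrophages −0.034 and 0.006 (reversed for YUMMER1.7), stroma 1.31 between tumours [0.92], and in YUMM1.7 macrophages the inflammatory list −0.031 [0.18] and the type I interferon list −0.079 [0.11]. Leaving out the shallow clusters 13 and 24, chosen after seeing the data like all single-cluster settings here, gave monocytes 1.32 and 1.38, migratory DCs −0.84 and −0.97, and macrophages 0.38 and 0.56 (reversed). With cluster 21 counted as stroma, stroma was 6.77 over naive [5.47] and 2.10 between tumours, and 1.31 with it left out. Thinning to 2000 UMIs reversed Rgs5 in blood endothelium to −0.69 [2.03], Ncam2 in lymphatic endothelium to 0.067 [−1.44] and Socs2 in plasma cells to −0.059 [0.81]. It also reversed the inflammatory list in migratory DCs to 0.044 [−0.34] and cDC1 to 0.13 [−0.50] for YUMM1.7 over naive, and between tumours to −0.10 [0.18] in cDC1, −0.38 [0.68] in blood endothelium and −0.057 [0.26] in fibroblastic cells. Between tumours it reversed proliferation to −0.032 [0.19] in migratory DCs and 0.036 [−0.48] in blood endothelium, the angiogenic list to −0.20 [0.14] and the checkpoint list to −0.054 [0.21] in fibroblastic cells, and leukocyte adhesion to −0.05 [0.20] in lymphatic endothelium; the type I interferon list in YUMM1.7 macrophages was −0.046. Thinning moved MHC class II in YUMM1.7 migratory DCs to 0.65 [0.44], MHC class I in cDC1 to 0.10 [0.21], and type I interferon over naive to 0.98 [1.25] in cDC1 and 0.91 [0.54] in neutrophils of the YUMMER1.7 library. With members of at least 50 UMIs, the YUMMER1.7 values in cDC1 were 0.10 [−0.60] for the reticular list and 0.92 for type I interferon, and the inflammatory list in cDC2 was 0.015 [−0.23] between tumours. In neutrophil cluster 3 alone, leukocyte adhesion was 0.20 [−0.46], proliferation −0.31 [1.93] and type I interferon 0.85; the proliferation value came from cluster 4. In migratory DC cluster 5 alone, maturation was −0.11 [0.22] and −0.15 [0.28], MHC class II 0.17 and 0.14 [0.49], hypoxia −0.06 [0.15] for YUMM1.7, and between tumours MHC class I 0.035 [0.25], the inflammatory list 0.008 [−0.23] and type I interferon −0.008 [0.13]. In cluster 6 alone MHC class II was −0.58 and −0.26 (reversed), so the class values depend on the mix of clusters. Without cluster 8, type I interferon in YUMM1.7 monocytes was 0.42 [0.54]. Depth limits the classes with few cells.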

Other observations

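In the enriched fraction B cells of the YUMMER1.7 library held more Slpi, a secreted protease inhibitor, at 82.4, 188 and 493 CPM in the naive, YUMM1.7 and YUMMER1.7 libraries. Slpi was also a marker of plasma cells, which made up 0.342%, 0.747% and 0.974% of kept cells there. Free RNA, or plasma cells among the B cells, was therefore not excluded. In migratory DCs of the depleted fraction Prkg1 stood at 3.32, 149 and 171 CPM, whereas in those of the enriched fraction it stood at 19.2, 52.2 and 23.1 CPM. Extracellular matrix genes in B cells of the depleted fraction rose likewise (9.41, 153 and 285 CPM), so free stromal RNA was not excluded for Prkg1 there. In plasma cells Atp1b1, a subunit of the sodium pump, stood at 16.7, 78.2 and 67.6 CPM. Haemoglobin transcripts made up 309 CPM of the naive depleted library, against 5.62 and 11.4 CPM in the YUMM1.7 and YUMMER1.7 libraries. Ptprc, which encodes CD45, stood at 1165, 688 and 467 CPM in the depleted libraries.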
